A study of Mus musculus with 14 samples.

How the data were processed

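RNA of sorted cortical microglia was measured in 14 libraries of 7 groups, sham and 6 times after stroke, with 2 libraries per group. Groups and replicate numbers were taken from the sample titles. The sort markers and gate and the time at which sham animals were sampled are not given in the sources used here. No label says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

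The values are whole-number counts per gene that the authors deposited, in 1 table of the series and in 1 file per library. All 14084 values agreed between the table and each of the 14 files, in which 23 gene symbols had been turned into dates. Symbols were therefore taken from the table. Bowtie2 2.3.4.2, HTSeq 0.6.1 and the mm9 mouse genome build are named in the submitters' processing notes. The annotation, the strand setting and the handling of multiply aligned reads are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Because the reference used here is another build (GRCm38), no coordinates are printed.

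Total counts of replicates 1 and 2 were 15254983 and 100625099 for sham, 20440442 and 144553466 for day 1, 16328102 and 149992816 for day 3, 18500290 and 134103031 for day 7, 16939261 and 116539697 for day 21, 27842666 and 183895519 for day 60 and 28758420 and 191692779 for day 90. Replicate 2 was 6.60 to 9.19 times as deep as replicate 1. Floors and fold bounds cover counting error only. A gene without a count in all libraries of a group was set to a floor of 3 counts over the group, its fold is given as at least that large, and for genes with 1 to 3 counts in a group levels or counts are given in place of a fold. List medians are given with genes at 0 placed at their bound. Libraries of a group were compared by a chi-square test of their counts, and the statistic per degree of freedom was at least 431 in every pair.

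Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The filter by group left 13861 genes and removed 223. Libraries were scaled by TMM factors and 1 quasi-likelihood model with a mean per group and robust dispersions was fitted to all 14 libraries, leaving 7 residual degrees of freedom. The common biological coefficient of variation was 0.639. Each of the 6 times was tested against sham, each of 5 neighbouring pairs of times against each other, the mean of the 3 late times against that of the 3 early times and against sham, and all 7 groups jointly. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, with no fold limit. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM of genes are TMM-scaled, sums over lists are not, and log2 CPM use a prior count of 2.

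Fixed lists, 23 of genes and 13 of cell type markers, were tested as sets with camera at a preset correlation of 0.01, adjusted over 216 tests against sham and over 36 tests between early and late times. Of the 252 tests 139 passed, and with an estimated correlation 1 did, the B cell list between early and late times. The adjusted p with an estimated correlation therefore stands beside each list given here that passed, and not all lists that passed are given. Members called by edgeR are counted beside the number called when p was adjusted within the list alone. A list's median, mean and test differed in sign in 26 of the 252 tests, of which camera called 0. Lists share members: 19 of 30 disease-associated microglia genes, 15 of 16 M1 markers, 5 of 14 border-associated macrophage markers and 2 of 15 neutrophil markers are also in another list. Markers of the border-associated macrophage and dendritic cell lists such as Mrc1 and Siglech are also transcribed in microglia.

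The named genes follow a rule fixed with the lists, groups, tests and alternatives before the data were examined. It takes, for each time against sham, the 6 higher and 6 lower called genes with the largest log2 fold change among those with a mean log2 CPM of at least 3 and both libraries of that time on the same side of both sham libraries. It also takes up to 4 called members of each list in each comparison by size of change, a panel of 24 genes given at every time whatever its result, and the 5 higher and 5 lower genes of the other comparisons. Clec7a, Ccl6, Kif23, Selplg and F13a1, list members that moved against their list where the rule does not reach them, and the genes named in the closing section outside these comparisons were chosen after their values were seen. Some genes that the rule takes are not reported here.

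Near-identical copies were sought by comparing 50-base words of the transcripts of all genes, 1 in 8 sampled, and a gene with at least 50% of its words in another gene was taken to have a copy. Transcripts were found for 14036 of the 14084 genes (99.7%), 514 of them through synonyms, and 293 (2.09%) had a copy. Among the named genes these are Hspa1a and Hspa1b, which share 62.7% and 62.9%, so their values are uncertain.

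The tests were tried on simulated data first. With counts drawn for day 1 against sham over 13596 genes, 50 of them changed at each fold, edgeR recovered 0% of 2-fold, 2% of 4-fold, 22% of 8-fold and 60% of 16-fold changes, with 6.67% false calls. DESeq2 recovered 0%, 24%, 56% and 78% with 43.2% false calls, and limma-voom 0%, 0%, 14% and 54% with 2.86%. For day 3 against sham over 13861 genes, camera found a list of 25 genes shifted 2-fold at an unadjusted 0.05, which 2.5% of 200 unchanged lists passed. This does not cover lists whose members are correlated.

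Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter of at least 1 CPM in 4 libraries, DESeq2, limma-voom, a test against a minimum fold change of 2 (glmTreat), libraries thinned to equal totals, fits of only the libraries compared, the replicate number as a block with and without RLE scaling, and leaving out each library in turn. Set tests were repeated with an estimated correlation, with fry, with shared members removed, with the block and with RLE scaling. Leaving out the day 21 libraries or genes with a near-identical copy was added after seeing the data. When 1 library of a pair is left out, the remaining library is assumed to vary like the other groups.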

Results

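Microglia, the resident macrophages of the brain, were collected by cell sorting from the cerebral cortex of C57BL/6 mice, and gene counts from their RNA were compared across a time course of focal ischemia. Stroke animals had a permanent ligation of the distal middle cerebral artery combined with a brief closure of both common carotid arteries, while sham animals had a lesion of the skull surface. The 7 groups were sham and days 1, 3, 7, 21, 60 and 90 after stroke, with 2 libraries in each and 14 in all. Total counts lay between 15254983 and 28758420 in the 7 libraries numbered replicate 1 and between 100625099 and 191692779 in the 7 numbered replicate 2. At these totals 3 counts correspond to 0.104 to 0.197 counts-per-million units (CPM) in replicate 1 and to 0.0157 to 0.0298 CPM in replicate 2. Levels of genes below are TMM-scaled CPM and sums over lists are CPM of the total counts without TMM factors, each as mean ± SD over the libraries of a group (n = 2 for each group), and log2 fold changes are given with ± 1 standard error.

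The first principal component of the log2 CPM values held 28.5% of the variance and set both sham libraries apart from the 12 stroke libraries. The second held 18.0% and separated the replicate numbers, with every replicate 1 library at or above 12.4 and every replicate 2 library at or below -27.9. Libraries of 1 group correlated over genes with r between 0.824 at day 21 and 0.942 at day 90, and no pair agreed within sampling noise. Because depth and replicate number divide the libraries in the same way, fold changes against sham were also taken within each replicate number. Over all genes, those of replicate 1 and of replicate 2 correlated with r of 0.432, 0.576, 0.799, 0.572, 0.733 and 0.789 for days 1, 3, 7, 21, 60 and 90, and the share of all genes with the same sign in both was 57.5, 64.3, 82.3, 71.5, 80.3 and 80.2%.

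**Figure D1:**
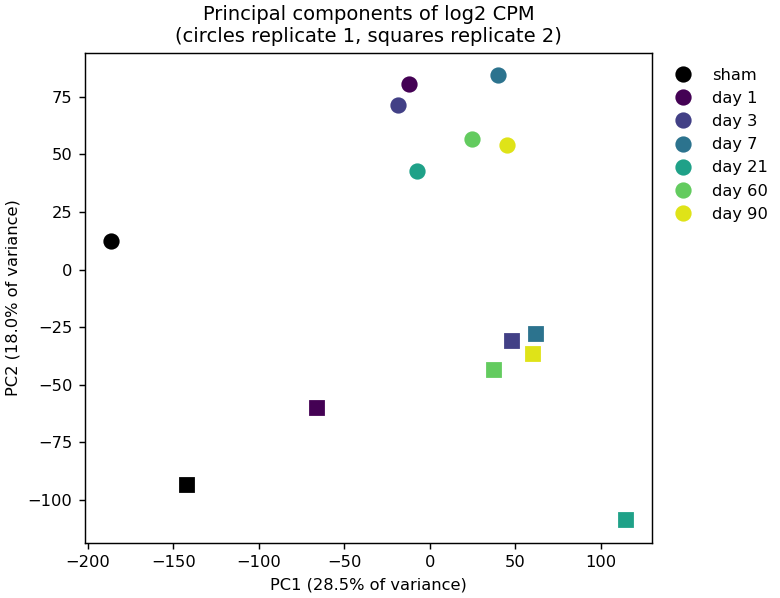
Principal components of log2 CPM for the 14 libraries, with the percent of variance on each axis, colour for the group and marker shape for the replicate number. Sham lies apart from the stroke libraries on the first component, and replicate 1 lies above replicate 2 on the second.

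Levels of microglial identity markers and other genes are given in the order sham and days 1, 3, 7, 21, 60 and 90. Tmem119, a microglial membrane protein gene, had 9.70 ± 10.2, 179.9 ± 195, 280.5 ± 12.8, 279 ± 94.2, 275 ± 106, 143 ± 62.5 and 148 ± 78.9 CPM and was called higher than sham at all 6 times. P2ry12, the purinergic receptor that guides microglial processes, had 32.5 ± 21.1, 57.0 ± 48.1, 185 ± 92.7, 118 ± 38.6, 250 ± 152, 140.5 ± 54.1 and 159.9 ± 54.1 CPM and was called at day 21 alone. Sall1, a transcription factor of microglial identity, had 0.319 ± 0.149, 1.53 ± 0.646, 11.4 ± 11.3, 3.86 ± 1.00, 30.6 ± 22.8, 3.25 ± 1.29 and 4.13 ± 1.25 CPM and was called at the 5 times from day 3. Cx3cr1, the fractalkine receptor, had 271 ± 172, 157 ± 147, 263 ± 98.5, 523 ± 231, 669.6 ± 103, 169 ± 93.3 and 443 ± 259 CPM and was called at no time by edgeR. Ccr2, the chemokine receptor of classical monocytes, had 762 ± 279, 353 ± 61.6, 266 ± 143, 143 ± 61.3, 457 ± 615, 218 ± 108 and 294 ± 151 CPM. Fos, an immediate early transcription factor, had 4504 ± 349, 4254 ± 1894, 3453 ± 1580.4, 1976 ± 219, 3463 ± 828, 2179 ± 366 and 1443 ± 354 CPM, and neither was called by edgeR at any time against sham.

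Genes of lipid handling and of disease-associated microglia reached their means at different times. Levels keep that order. Spp1, which encodes osteopontin, had 40.5 ± 43.0, 16485 ± 15124, 9931 ± 3844, 70944 ± 5953, 3134 ± 2916, 5339.5 ± 182 and 2286 ± 201 CPM. Gpnmb, a glycoprotein of phagocytic macrophages, had 2.67 ± 3.18, 3160.5 ± 4176, 2925 ± 742, 15251 ± 1212, 1473 ± 1081, 7342 ± 532 and 7824 ± 109 CPM. Trem2, a lipid-sensing receptor, had 22.6 ± 7.63, 788 ± 853, 991 ± 118, 1301 ± 526, 1512 ± 1676, 2307 ± 1512 and 1169 ± 469.7 CPM. These 3 genes were called at all 6 times, as was Igf1. This growth factor gene had 0.454 ± 0.299, 35.7 ± 45.8, 33.8 ± 8.85, 349.9 ± 26.5, 87.7 ± 67.1, 375 ± 39.4 and 236 ± 24.7 CPM. Apoe, the main brain apolipoprotein, had 1693 ± 202, 22722 ± 28831, 23685 ± 13980, 44981 ± 20808, 63494 ± 64383, 88295 ± 4639.7 and 36591 ± 283 CPM, called from day 7. Lpl, lipoprotein lipase, had 115 ± 15.3, 130.3 ± 14.7, 104 ± 24.6, 981 ± 189.9, 799 ± 823, 4527 ± 133 and 4697 ± 483 CPM, also called from day 7. The cystatin gene Cst7 had 1.82 ± 0.254, 18.7 ± 14.3, 36.4 ± 10.6, 57.3 ± 28.4, 499 ± 555, 34.7 ± 1.57 and 20.6 ± 2.25 CPM, called from day 3. Cd74, the invariant chain of MHC class II, had 3089 ± 1458, 7913 ± 2214, 6007 ± 858, 6451 ± 2124, 9798 ± 8028, 50974 ± 23818 and 27021 ± 11305 CPM, called at days 60 and 90.

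Inflammatory, interferon and division genes are listed in the same order of groups. Tnf had 27.9 ± 8.44, 1089 ± 102, 1328 ± 567, 184 ± 32.8, 339 ± 272, 432 ± 14.6 and 78.5 ± 13.6 CPM and was called at every time except day 90. Il1b had 6691 ± 1553, 8800.2 ± 5014, 7538 ± 5095, 394 ± 55.6, 2206 ± 240.1, 3102 ± 682 and 1251 ± 78.6 CPM, lower than sham by edgeR at days 7 and 90. Ccl2, a monocyte-attracting chemokine, had 24.6 ± 13.4, 331 ± 18.7, 295 ± 266, 72.2 ± 0.00993, 19.2 ± 0.0125, 21.0 ± 2.48 and 5.36 ± 0.615 CPM. Hmox1, the heme-degrading oxygenase, had 72.6 ± 22.0, 1743 ± 455, 1179 ± 1274, 190 ± 60.8, 122 ± 27.4, 245 ± 1.72 and 162 ± 2.47 CPM, both called at days 1 and 3. Isg15, an interferon-induced ubiquitin-like modifier, had 44.8 ± 3.78, 36.3 ± 12.5, 35.8 ± 23.4, 13.8 ± 3.02, 21.1 ± 12.3, 63.5 ± 9.41 and 5.47 ± 1.84 CPM. Ifit3, another interferon-induced gene, had 124 ± 4.19, 40.1 ± 25.2, 42.8 ± 3.45, 66.7 ± 18.7, 83.7 ± 12.7, 205 ± 2.93 and 29.5 ± 4.16 CPM, both called lower at day 90. C3, the central complement component, had 344 ± 79.1, 143 ± 165, 61.2 ± 21.8, 40.8 ± 12.5, 238 ± 40.0, 104 ± 28.4 and 114 ± 55.0 CPM and was called lower at day 7. Top2a, topoisomerase II alpha of dividing cells, had 1.51 ± 0.0979, 4.27 ± 3.11, 29.4 ± 27.9, 59.1 ± 10.6, 7.95 ± 8.43, 7.44 ± 0.893 and 30.0 ± 9.10 CPM, called at days 3, 7 and 90. Mki67, a proliferation marker, had 7.75 ± 4.29, 6.71 ± 1.19, 16.8 ± 9.20, 29.2 ± 7.99, 8.07 ± 4.93, 5.69 ± 2.89 and 16.8 ± 4.16 CPM, called at no time by edgeR.

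**Figure D2:**
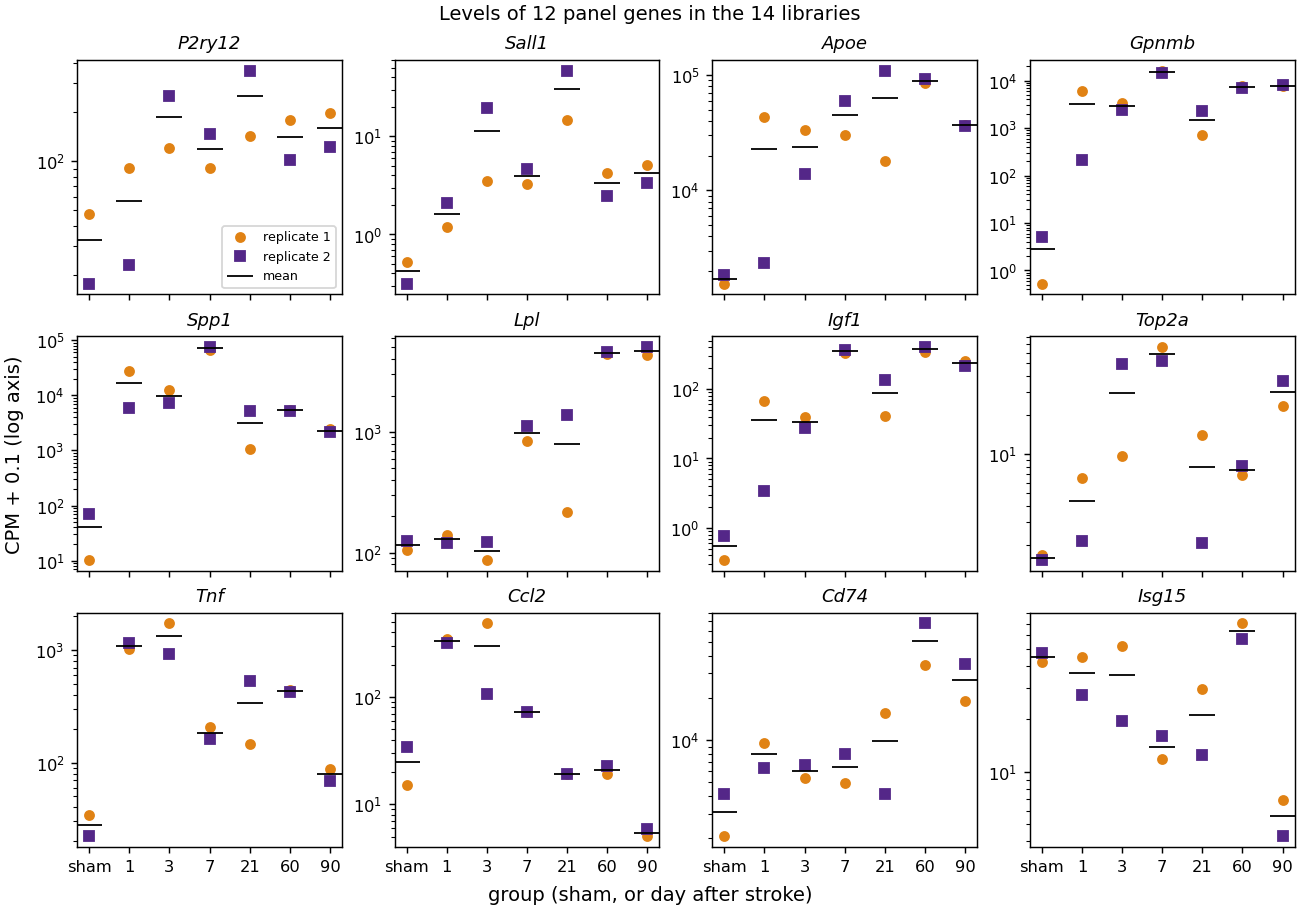
Levels of 12 panel genes by group in TMM-scaled CPM + 0.1 on a log axis, each point 1 library and each bar a group mean. Spp1 and Gpnmb have their highest means at day 7, Cd74 at day 60 and Lpl at day 90.

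The number of genes called against sham by edgeR at an adjusted p under 0.05 among 13861 tested was 631 at day 1, 1147 at day 3, 1751 at day 7, 892 at day 21, 1088 at day 60 and 1089 at day 90. All 6 counts rest on the same 2 sham libraries, whose other differences from the stroke libraries are given with each time, and without 1 of them the counts fell to between 68 and 413. Without sham replicate 1 the 6 counts, in order of time, were 92, 225, 390, 153, 132 and 187, and without sham replicate 2 they were 76, 228, 413, 68, 189 and 129. With upper-quartile scaling the median of all genes moved by 0.125 log2 units at day 3, 0.147 at day 7, 0.215 at day 21, 0.102 at day 60 and 0.203 at day 90.

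**Figure D3:**
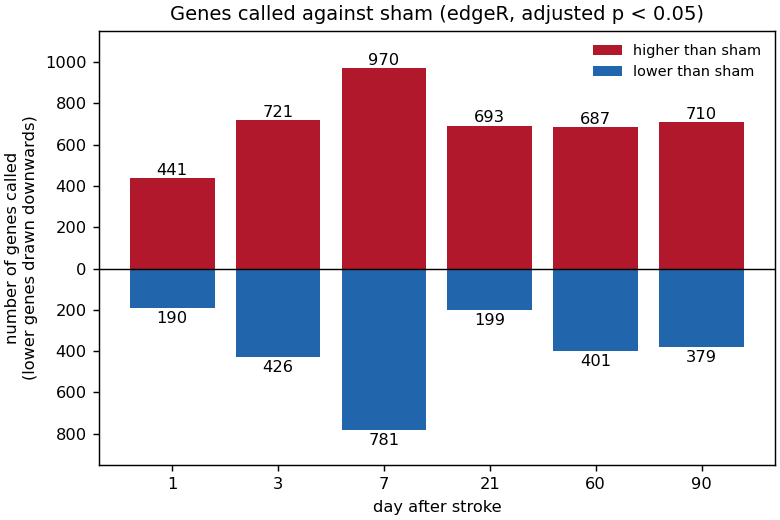
Number of genes called higher (up) and lower (down) than sham by edgeR at each time after stroke, at an adjusted p under 0.05. Day 7 has the most calls, 970 higher and 781 lower, and day 1 the fewest, 441 and 190.

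The comparison of day 1 with sham asked which genes differed in the acute phase. Arg1, which encodes arginase and is often used as a marker of alternative macrophage activation, rose (12.77 ± 1.57, edgeR adjusted p = 0.00186), to 2516 ± 1675 CPM against 0.335 ± 0.216 CPM in sham. Ifnb1, the gene of interferon beta, was at least 465-fold higher (edgeR adjusted p = 0.00248) and the chemokine gene Ccl8 at least 130.4-fold higher (adjusted p = 0.0309), each against no count in sham. Of the 25 inflammatory cytokine and NF-kB target genes 6 rose (8 adjusted within the list), among them Il1a (8.46 ± 1.00, edgeR adjusted p = 0.00153), Tnf (5.29 ± 0.69, adjusted p = 0.00234) and Nos2 (8.75 ± 1.67, adjusted p = 0.0143). The cytokine and NF-kB list had camera adjusted p = 0.000451, or 0.378 at an estimated correlation. Of the 19 chemokine genes 12 rose (14 adjusted within the list), with Ccl7 (8.57 ± 1.01, edgeR adjusted p = 0.00153), Cxcl1 (8.31 ± 1.76, adjusted p = 0.0257) and Ccl2 (3.75 ± 0.66, adjusted p = 0.0101) as examples. The chemokine list had camera adjusted p = 3.44e-09, or 0.226 at an estimated correlation. Complement genes of the C1q recognition molecule rose from low sham levels, C1qb to 4813 ± 6067 CPM against 11.7 ± 6.70 CPM and C1qa to 1654 ± 2038 CPM against 5.64 ± 4.21 CPM. Of 15 complement genes 4 rose (4 adjusted within the list). The complement list had camera adjusted p = 0.0683. Neutrophil marker transcripts summed to 5067 ± 5117 CPM at day 1 and to 28338 ± 7799 CPM in sham, and erythroid ones to 2.29 ± 3.03 and 204 ± 4.59 CPM.

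Among the 30 genes of disease-associated microglia 9 rose and 1 fell (18 and 1 adjusted within the list), with Gpnmb (10.18 ± 1.76, edgeR adjusted p = 0.00911), Spp1 (8.67 ± 1.33, adjusted p = 0.00543) and Igf1 (6.20 ± 1.22, adjusted p = 0.0165) higher and the beta-glucan receptor gene Clec7a (-2.30 ± 0.58, adjusted p = 0.0467) lower. The disease-associated list had camera adjusted p = 2.79e-06, or 0.394 at an estimated correlation. Of the 25 homeostatic microglia genes 4 rose (8 higher and 1 lower adjusted within the list), namely Fcrls, Olfml3, Fscn1 and Tmem119, the first from 7.20 ± 4.48 CPM to 690 ± 684 CPM. The homeostatic list had camera adjusted p = 0.00302, or 0.47 at an estimated correlation. Lysosomal genes gave 8 higher of 30 (17 adjusted within the list), among them the cathepsin genes Ctsl (4.47 ± 0.84, edgeR adjusted p = 0.0132) and Ctsb (3.56 ± 0.80, adjusted p = 0.0281). The lysosome list had camera adjusted p = 3.94e-08, or 0.394 at an estimated correlation. Of the 22 oxidative stress and iron genes 6 rose and 1 fell (13 and 2 adjusted within the list), with Hmox1 (4.58 ± 0.81, edgeR adjusted p = 0.0101) and the glutathione synthesis gene Gclm (3.43 ± 0.67, adjusted p = 0.0155) higher and Slc40a1, the iron exporter ferroportin, lower (-3.72 ± 0.66, adjusted p = 0.0101). The oxidative stress list had camera adjusted p = 0.000607, or 0.317 at an estimated correlation. Of 20 unfolded protein response genes 4 rose (7 higher and 1 lower adjusted within the list). The list had camera adjusted p = 0.00559, or 0.243 at an estimated correlation. Of 23 lipid transport genes 4 rose (9 higher and 1 lower adjusted within the list), including the lipid droplet gene Plin2 (4.37 ± 0.56, edgeR adjusted p = 0.00223). The lipid transport list had camera adjusted p = 0.00118, or 0.394 at an estimated correlation. Of 21 glycolysis genes 2 rose (9 adjusted within the list), Tpi1 and Vegfa. The glycolysis list had camera adjusted p = 0.00289, or 0.394 at an estimated correlation. Interferon response genes went the other way: of 27, 1 rose and 4 fell (1 and 8 adjusted within the list), Cxcl10 higher (3.46 ± 0.59, edgeR adjusted p = 0.00875) and Cmpk2 (-2.93 ± 0.61, adjusted p = 0.0204) lower. The interferon response list had camera adjusted p = 0.000208, or 0.293 at an estimated correlation. The matrix protease gene Mmp14 rose (7.52 ± 0.71, edgeR adjusted p = 0.000387). Of 22 matrix genes 5 rose (10 adjusted within the list). The matrix list had camera adjusted p = 0.000135, or 0.209 at an estimated correlation. Of 17 growth factor genes 4 rose (7 adjusted within the list), among them Gdf15 (7.04 ± 1.08, edgeR adjusted p = 0.00543). The growth factor list had camera adjusted p = 1.44e-05, or 0.0906 at an estimated correlation. Of 36 cell cycle genes 3 rose and 1 fell (8 and 1 adjusted within the list). The cell cycle list had camera adjusted p = 0.00114, or 0.589 at an estimated correlation.

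Markers of other cell types moved at day 1 in both directions. Of the 14 border-associated macrophage genes 8 rose (10 adjusted within the list), with Stab1 (5.48 ± 0.71, edgeR adjusted p = 0.00234) and Ms4a7 (6.70 ± 1.14, adjusted p = 0.00881). The list had camera adjusted p = 9.2e-07, or 0.0906 at an estimated correlation. Of the 10 B cell genes 5 fell (7 adjusted within the list), with Ms4a1, the CD20 gene, (-6.07 ± 0.95, edgeR adjusted p = 0.00593) and Cd79a (-5.68 ± 0.93, adjusted p = 0.00691), and Blk at least 282-fold lower (adjusted p = 0.00687). The B cell list had camera adjusted p = 2.47e-07, or 0.107 at an estimated correlation. Of 18 T and NK cell genes 1 rose and 3 fell (1 and 9 adjusted within the list), Il7r higher (5.94 ± 0.78, edgeR adjusted p = 0.00236) and the granzyme gene Gzma lower (-4.02 ± 0.91, adjusted p = 0.0282). The list had camera adjusted p = 6.64e-05, or 0.293 at an estimated correlation. Of 15 neutrophil genes none was called by edgeR (2 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom and 0 adjusted within the list), with a bounded median log2 fold change of -2.36. The list had camera adjusted p = 0.00369, or 0.514 at an estimated correlation. In the 17-gene monocyte list no member was called by edgeR (5 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom and 0 adjusted within the list). The monocyte list had camera adjusted p = 0.122. In total 631 genes passed at day 1, 441 higher and 190 lower, and the higher share of 69.9% was 57.3% of 1848 genes with DESeq2, and limma-voom gave 283 higher and 264 lower. The count was 266 against a minimum fold change of 2, 1093 with the day 21 libraries left out of the fit. Single libraries left out gave 92 or 76 without sham replicate 1 or 2, 273 or 947 without day 1 replicate 1 or 2, 1058 or 1098 without day 21 replicate 1 or 2 and 367 without either day 90 library.

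At day 3 genes of inflammation and of cell division were above sham. Of the 36 cell cycle genes 19 rose and 1 fell (26 and 1 adjusted within the list), among them the mitotic kinase gene Plk1 (6.98 ± 1.32, edgeR adjusted p = 0.00989), Cdk1 (5.65 ± 0.95, adjusted p = 0.00615) and Ccnb2 (5.32 ± 0.95, adjusted p = 0.00789), and the gene that fell was Kif23 (-3.87 ± 1.02, adjusted p = 0.0376), a kinesin of the mitotic midzone. Camera gave the cell cycle list adjusted p = 8.45e-09, or 0.394 at an estimated correlation. Arg1 (12.03 ± 1.54, edgeR adjusted p = 0.00172), Il1a (8.80 ± 1.01, adjusted p = 0.00114) and Tnf (5.57 ± 0.70, adjusted p = 0.00154) were higher, and Ifnb1 was at least 933-fold higher (adjusted p = 0.00154). Of the 19 chemokine genes 12 rose (13 higher and 1 lower adjusted within the list), including Ccl7 (8.60 ± 1.01, edgeR adjusted p = 0.00114) and Ccl12 (7.72 ± 1.25, adjusted p = 0.00513). Camera gave the chemokine list adjusted p = 2.91e-07, or 0.28 at an estimated correlation. Of the 25 cytokine and NF-kB target genes 6 rose (9 higher and 2 lower adjusted within the list). Camera gave the cytokine and NF-kB list adjusted p = 0.004, or 0.394 at an estimated correlation. Of 25 homeostatic genes 13 rose (16 higher and 1 lower adjusted within the list), with Fcrls at 1339 ± 585 CPM against 7.20 ± 4.48 CPM and Sall1 higher (5.24 ± 0.99, edgeR adjusted p = 0.00964). Camera gave the homeostatic list adjusted p = 5.15e-06, or 0.386 at an estimated correlation. Neutrophil marker transcripts summed to 2723 ± 2353 CPM at day 3 and erythroid ones to 0.328 ± 0.229 CPM, with the sham sums given above.

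Of 30 disease-associated genes 12 rose and 1 fell (18 and 2 adjusted within the list), with Gpnmb (10.07 ± 1.75, edgeR adjusted p = 0.00696) and Spp1 (7.93 ± 1.29, adjusted p = 0.00545) higher and Clec7a (-2.57 ± 0.59, adjusted p = 0.0231) lower. Camera gave the disease-associated list adjusted p = 3.23e-05, or 0.397 at an estimated correlation. Of 24 phagocytic receptor genes 8 rose and 1 fell (10 and 1 adjusted within the list), led by Gas6, a bridging ligand of the Mertk receptor, (8.40 ± 1.17, edgeR adjusted p = 0.00254) and Mertk (6.27 ± 0.85, adjusted p = 0.00228). The phagocytic receptor list had camera adjusted p = 0.00404, or 0.185 at an estimated correlation. Of 27 interferon response genes 1 rose and 5 fell (2 and 13 adjusted within the list), Cmpk2 (-3.75 ± 0.63, edgeR adjusted p = 0.00615) and Gbp2 (-2.94 ± 0.76, adjusted p = 0.0345) among the lower and Cxcl10 (3.68 ± 0.59, adjusted p = 0.0052) the higher. Camera gave the interferon response list adjusted p = 2e-05, or 0.235 at an estimated correlation. Of 20 unfolded protein response genes 6 rose and 1 fell (8 and 1 adjusted within the list), the chaperone gene Pdia4 higher (2.16 ± 0.39, edgeR adjusted p = 0.00807) and Chac1, a glutathione-degrading enzyme gene induced by stress, lower (-3.77 ± 1.00, adjusted p = 0.0394). Camera gave the unfolded protein response list adjusted p = 0.0362, or 0.373 at an estimated correlation. Of 15 endothelial genes 3 rose (7 higher and 1 lower adjusted within the list), including the VEGF receptor gene Kdr from 0.150 ± 0.0446 CPM to 11.9 ± 11.2 CPM. The endothelial list had camera adjusted p = 0.00322, or 0.44 at an estimated correlation. Of 10 B cell genes 4 fell (6 adjusted within the list), Ms4a1 (-7.58 ± 1.03, edgeR adjusted p = 0.00228) among them. Camera gave the B cell list adjusted p = 6.9e-06, or 0.136 at an estimated correlation. Alas2, the first enzyme of heme synthesis in red cell precursors, fell (-9.84 ± 2.18, edgeR adjusted p = 0.0247). In total 1147 genes passed, 721 higher and 426 lower, against 2639 with DESeq2 and 504 against a minimum fold change of 2. The balance turned with limma-voom, 608 higher and 676 lower. With the day 21 libraries left out of the fit the count was 1802. Single libraries left out gave 225 or 228 without sham replicate 1 or 2, 611 or 391 without day 3 replicate 1 or 2 and 1785 or 1815 without day 21 replicate 1 or 2.

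At day 7 Spp1 and Gpnmb had their highest means of the series. Spp1 rose (10.77 ± 1.45, edgeR adjusted p = 0.002) to 70944 ± 5953 CPM against 40.5 ± 43.0 CPM, Gpnmb rose (12.45 ± 1.90, adjusted p = 0.00356) to 15251 ± 1212 CPM, and Igf1 rose (9.50 ± 1.40, adjusted p = 0.00312). Of the 30 disease-associated genes 15 rose and 1 fell (20 and 2 adjusted within the list), the gene that fell being the chemokine gene Ccl6 (-5.80 ± 0.87, edgeR adjusted p = 0.00327). The disease-associated list had camera adjusted p = 6.83e-07, or 0.386 at an estimated correlation. Of 36 cell cycle genes 25 rose (29 higher and 1 lower adjusted within the list), with Ccnb2 (6.93 ± 1.02, edgeR adjusted p = 0.00305), Cdk1 (6.27 ± 0.98, adjusted p = 0.00388) and Top2a (5.30 ± 1.04, adjusted p = 0.00953). The cell cycle list had camera adjusted p = 2.97e-14, or 0.295 at an estimated correlation. Of 30 lysosome genes 14 rose (20 adjusted within the list), including the proton pump subunit gene Atp6v0d2 (11.64 ± 1.90, edgeR adjusted p = 0.00561) and the protease gene Ctsd (4.55 ± 0.94, adjusted p = 0.0122). Camera gave the lysosome list adjusted p = 1.12e-08, or 0.388 at an estimated correlation. Of 23 lipid transport genes 8 rose (12 higher and 1 lower adjusted within the list), with Apoe (4.73 ± 1.26, edgeR adjusted p = 0.0314), Lpl (3.09 ± 0.72, adjusted p = 0.0189) and the cholesterol exporter gene Abca1 (5.01 ± 0.64, adjusted p = 0.00178). Camera gave the lipid transport list adjusted p = 0.000373, or 0.388 at an estimated correlation. Of 25 homeostatic genes 13 rose and 1 fell (15 and 1 adjusted within the list), Tmem119 higher (4.86 ± 1.08, edgeR adjusted p = 0.0159) and the selectin ligand gene Selplg lower (-2.32 ± 0.56, adjusted p = 0.0223). The homeostatic list had camera adjusted p = 3.17e-05, or 0.394 at an estimated correlation. Neutrophil marker transcripts had their lowest sum of the series at day 7, 689 ± 417 CPM, and erythroid ones summed to 0.141 ± 0.0303 CPM.

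Lower at day 7 were Il1b (-4.09 ± 0.67, edgeR adjusted p = 0.00484), the inflammasome sensor gene Nlrp3 (-3.20 ± 0.73, adjusted p = 0.0174) and the complement gene C3 (-3.08 ± 0.84, adjusted p = 0.0339), while Tnf (2.72 ± 0.61, adjusted p = 0.0167) and Il1a (5.80 ± 0.89, adjusted p = 0.00362) were higher than sham. Of 25 cytokine and NF-kB target genes 3 rose and 3 fell (3 and 4 adjusted within the list). The cytokine and NF-kB list had camera adjusted p = 0.229. Of 22 immediate early genes 1 rose and 8 fell (2 and 10 adjusted within the list), Klf2 (-4.55 ± 0.78, edgeR adjusted p = 0.00568) and Ier2 (-2.58 ± 0.60, adjusted p = 0.0191) among them, and the gene that rose was Hspa1a, whose count is uncertain because it shares sequence with a near-identical copy. The immediate early list had camera adjusted p = 0.00574, or 0.57 at an estimated correlation. Of 15 neutrophil genes 7 fell (10 adjusted within the list), among them S100a8 (-8.22 ± 2.08, edgeR adjusted p = 0.0295), the chemokine receptor gene Cxcr2 (-8.85 ± 1.79, adjusted p = 0.0137) and the gelatinase gene Mmp9 (-7.10 ± 1.51, adjusted p = 0.0144). Camera gave the neutrophil list adjusted p = 7.16e-07, or 0.373 at an estimated correlation. Of 17 monocyte genes 5 fell (7 adjusted within the list), including Plac8 (-5.03 ± 1.37, edgeR adjusted p = 0.0376). Camera gave the monocyte list adjusted p = 0.000204, or 0.421 at an estimated correlation. Slc40a1 fell (-5.41 ± 0.72, edgeR adjusted p = 0.00198). Of 27 interferon response genes 6 fell (2 higher and 14 lower adjusted within the list). The interferon response list had camera adjusted p = 0.000217, or 0.293 at an estimated correlation. Of 10 B cell genes 4 fell (1 higher and 8 lower adjusted within the list). The B cell list had camera adjusted p = 2.67e-05, or 0.136 at an estimated correlation. Of 14 border-associated macrophage genes 5 rose (6 adjusted within the list). Camera gave the border-associated macrophage list adjusted p = 0.00273, or 0.136 at an estimated correlation. In total 1751 genes passed, 970 higher and 781 lower, against 3172 with DESeq2 and 790 against a minimum fold change of 2. The balance turned with limma-voom, 896 higher and 970 lower, and without sham replicate 2, 198 higher and 215 lower. With 1 library left out the count was 390 or 413 without sham replicate 1 or 2 and 355 or 464 without day 7 replicate 1 or 2.

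At day 21, as at other times, homeostatic genes exceeded sham, which may hold less microglial RNA. Of 25, 15 rose (19 adjusted within the list), with Sall1 (6.66 ± 1.05, edgeR adjusted p = 0.00532), Fscn1 (8.05 ± 0.92, adjusted p = 0.00141) and P2ry12 (2.94 ± 0.78, adjusted p = 0.047). Camera gave the homeostatic list adjusted p = 2.19e-09, or 0.257 at an estimated correlation. Cst7 (8.09 ± 1.08, edgeR adjusted p = 0.00276), Gpnmb (9.08 ± 1.68, adjusted p = 0.0118) and Igf1 (7.50 ± 1.29, adjusted p = 0.00793) stood among 14 higher and 1 lower of 30 disease-associated genes (17 and 3 adjusted within the list), Ccl6 the lower 1 (-3.21 ± 0.77, adjusted p = 0.0323). Camera gave the disease-associated list adjusted p = 2.67e-05, or 0.394 at an estimated correlation. Of 19 chemokine genes 10 rose and 1 fell (12 and 2 adjusted within the list), Ccl12 higher (7.74 ± 1.25, edgeR adjusted p = 0.00587) and Ccl6 lower. The chemokine list had camera adjusted p = 7.6e-05, or 0.388 at an estimated correlation. Il12b, a subunit of interleukins 12 and 23, had 17.9 ± 0.575 CPM at day 21 and 2 counts in sham, and of 25 cytokine and NF-kB target genes 5 rose (8 higher and 2 lower adjusted within the list). Camera gave the cytokine and NF-kB list adjusted p = 0.0263, or 0.47 at an estimated correlation. Of 15 complement genes 6 rose (6 higher and 1 lower adjusted within the list), C1qa at 2664 ± 2122 CPM against 5.64 ± 4.21 CPM. Camera gave the complement list adjusted p = 0.029, or 0.243 at an estimated correlation. Neutrophil markers summed to 4660.3 ± 5216 CPM, dendritic cell ones to 1512 ± 1548 against 510.4 ± 83.4 CPM in sham, and erythroid ones to 0.325 ± 0.459 CPM.

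Of 36 cell cycle genes 2 rose and 1 fell (8 and 1 adjusted within the list) at day 21, Cdk1 (4.45 ± 0.91, edgeR adjusted p = 0.0168) and Plk1 (5.51 ± 1.26, adjusted p = 0.0267) higher and Kif23 (-4.47 ± 1.05, adjusted p = 0.0297) lower. Camera gave the cell cycle list adjusted p = 0.00257, or 0.595 at an estimated correlation. Of 27 interferon response genes 1 rose and 1 fell (1 and 1 adjusted within the list). Camera gave the interferon response list adjusted p = 0.0407, or 0.455 at an estimated correlation. Pparg, a lipid-sensing nuclear receptor gene, fell (-2.26 ± 0.44, edgeR adjusted p = 0.0141), as did the platelet chemokine gene Ppbp (-9.14 ± 1.81, adjusted p = 0.0172) and the monocyte receptor gene Cd300e (-5.76 ± 0.94, adjusted p = 0.00635). Of 15 endothelial genes 4 rose (8 adjusted within the list). Camera gave the endothelial list adjusted p = 0.000607, or 0.394 at an estimated correlation. Of 14 mural cell and fibroblast genes 2 rose (2 adjusted within the list). The mural cell and fibroblast list had camera adjusted p = 0.0256, or 0.455 at an estimated correlation. Of 15 astrocyte genes 2 rose (5 adjusted within the list), among them the glutamate transporter gene Slc1a3 (5.12 ± 1.05, edgeR adjusted p = 0.0175). The astrocyte list had camera adjusted p = 0.00106, or 0.394 at an estimated correlation. Of 12 oligodendrocyte genes 1 rose (3 higher and 1 lower adjusted within the list). The oligodendrocyte list had camera adjusted p = 0.0226, or 0.231 at an estimated correlation. Of 6 precursor genes 1 rose (1 adjusted within the list), Cspg4 (5.52 ± 1.25, edgeR adjusted p = 0.0264). The precursor list had camera adjusted p = 0.417. For 41 oxidative phosphorylation genes no member was called by edgeR (9 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom and 0 adjusted within the list), with a median log2 fold change of -1.23. The oxidative phosphorylation list had camera adjusted p = 0.000909, or 0.639 at an estimated correlation. In total 892 genes passed, 693 higher and 199 lower, a higher share of 77.7% that was 65.2% of 2461 genes with DESeq2, against 1696 with limma-voom (856 higher and 840 lower), 389 against a minimum fold change of 2, and 0 when only the 4 libraries of the comparison were fitted. With 1 library left out the count was 153 or 68 without sham replicate 1 or 2, 587 or 581 without day 7 replicate 1 or 2, 2410 or 277 without day 21 replicate 1 or 2, 532 or 538 without day 60 replicate 1 or 2 and 490 or 487 without day 90 replicate 1 or 2.

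At day 60 Mmp12 and genes of lipid transport and MHC class II presentation were above sham. Mmp12, the macrophage elastase gene, rose (12.93 ± 1.07, edgeR adjusted p = 0.000202) to 2713 ± 561 CPM against 0.323 ± 0.199 CPM. Lpl (5.30 ± 0.80, edgeR adjusted p = 0.00388), Apoe (5.70 ± 1.32, adjusted p = 0.026) and the phospholipid transfer gene Pltp (5.41 ± 1.04, adjusted p = 0.012) were among 12 higher of 23 lipid transport genes (15 higher and 1 lower adjusted within the list). The lipid transport list had camera adjusted p = 9.62e-07, or 0.259 at an estimated correlation. Of 12 MHC class II presentation genes 8 rose (9 higher and 1 lower adjusted within the list), with H2-Eb1 (5.50 ± 0.92, edgeR adjusted p = 0.00564), H2-Aa (5.11 ± 0.92, adjusted p = 0.00822) and Cd74 (4.04 ± 0.80, adjusted p = 0.0137). The MHC class II list had camera adjusted p = 2.59e-05, or 0.268 at an estimated correlation. The nonclassical class I gene H2-M2 was at least 1610-fold higher (edgeR adjusted p = 0.00916), and in the list of 14 class I genes 1 rose (1 adjusted within the list), H2-M3 (1.86 ± 0.46, adjusted p = 0.0332). The MHC class I list had camera adjusted p = 0.324. Of 19 chemokine genes 11 rose (14 adjusted within the list), Ccl8 at least 3842-fold higher (edgeR adjusted p = 0.00545) and Cxcl16 higher (8.18 ± 0.68, adjusted p = 0.000202). Camera gave the chemokine list adjusted p = 3.94e-08, or 0.257 at an estimated correlation. Of 30 disease-associated genes 18 rose and 1 fell (22 and 1 adjusted within the list), Igf1 (9.60 ± 1.40, edgeR adjusted p = 0.00348) and Trem2 (6.68 ± 1.25, adjusted p = 0.0105) among the higher and the growth factor gene Csf1 (-2.97 ± 0.80, adjusted p = 0.0421) the lower. The disease-associated list had camera adjusted p = 3.94e-08, or 0.349 at an estimated correlation. Of 25 homeostatic genes 8 rose (14 higher and 1 lower adjusted within the list). The homeostatic list had camera adjusted p = 0.000129, or 0.394 at an estimated correlation. Of 27 interferon response genes 2 rose (3 adjusted within the list). The interferon response list had camera adjusted p = 0.442. Neutrophil marker transcripts summed to 1061 ± 47.5 CPM, erythroid ones to 0.194 ± 0.0816 CPM, T and NK cell ones to 303 ± 55.6 CPM against 83.8 ± 22.4 CPM in sham, and B cell ones to 242 ± 25.8 CPM against 151 ± 11.5 CPM. Neuron ones summed to 605 ± 834 CPM and mural ones to 779.6 ± 934 CPM against 24.2 ± 5.27 and 115 ± 66.5 CPM in sham, both high in replicate 2 alone.

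Of 30 lysosome genes at day 60 12 rose (22 adjusted within the list), among them Ctsk (8.46 ± 1.57, edgeR adjusted p = 0.0121) and Ctsl (5.42 ± 0.88, adjusted p = 0.00528). The lysosome list had camera adjusted p = 3.44e-09, or 0.386 at an estimated correlation. Of 15 complement genes 6 rose (7 higher and 2 lower adjusted within the list), C1qb at 8806 ± 389 CPM against 11.7 ± 6.70 CPM. The complement list had camera adjusted p = 0.0207, or 0.222 at an estimated correlation. Of 16 classical M1 markers 6 rose (7 higher and 1 lower adjusted within the list), including Cxcl9 (6.11 ± 1.45, edgeR adjusted p = 0.0282) and Il6 (4.57 ± 1.04, adjusted p = 0.0242). The M1 list had camera adjusted p = 0.0355, or 0.388 at an estimated correlation. Of 16 M2 markers 3 rose (5 higher and 3 lower adjusted within the list), including Mrc1, the mannose receptor gene, (3.67 ± 0.43, edgeR adjusted p = 0.00106) and Pparg (2.05 ± 0.44, adjusted p = 0.0188). The M2 list had camera adjusted p = 0.548. Of 14 border-associated macrophage genes 6 rose and 1 fell (9 and 1 adjusted within the list), Ms4a7 (8.25 ± 1.22, edgeR adjusted p = 0.00353) among the higher and F13a1 (-3.93 ± 0.95, adjusted p = 0.0296) the lower. The border-associated macrophage list had camera adjusted p = 6.64e-05, or 0.0906 at an estimated correlation. Of 21 cholesterol synthesis genes 2 fell (2 adjusted within the list), Sqle (-3.08 ± 0.85, edgeR adjusted p = 0.0461) and Sc5d (-2.74 ± 0.58, adjusted p = 0.0177). The cholesterol biosynthesis list had camera adjusted p = 0.0443, or 0.451 at an estimated correlation. Klf2 fell (-4.79 ± 0.79, edgeR adjusted p = 0.00545), and of 15 neutrophil genes 2 fell (6 adjusted within the list). The neutrophil list had camera adjusted p = 0.000607, or 0.451 at an estimated correlation. The T and NK cell gene Il7r rose (8.04 ± 0.85, edgeR adjusted p = 0.000594) and the milk fat globule gene Mfge8, a bridge in engulfment, rose (4.26 ± 0.46, adjusted p = 0.000594). In total 1088 genes passed, 687 higher and 401 lower, and the higher share of 63.1% was 52.5% of 2653 genes with DESeq2, and limma-voom gave 607 higher and 601 lower. The count was 409 against a minimum fold change of 2, 1749 with day 21 left out of the fit, 1675 with only the 4 libraries fitted (835 higher and 840 lower). Single libraries left out gave 132 or 189 without sham replicate 1 or 2, 1717 or 1750 without day 21 replicate 1 or 2, 263 or 220 without day 60 replicate 1 or 2 and 601 or 602 without day 90 replicate 1 or 2.

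At day 90 Mmp12 and lipid transport genes were above sham and interferon response genes below. Mmp12 (12.86 ± 1.07, edgeR adjusted p = 0.000218), Gpnmb (11.49 ± 1.84, adjusted p = 0.00491), Lpl (5.35 ± 0.80, adjusted p = 0.0045) and Mfge8 (6.10 ± 0.50, adjusted p = 0.000218) rose, and H2-M2 was at least 4050.1-fold higher (adjusted p = 0.00751). Of 27 interferon response genes 11 fell (1 higher and 16 lower adjusted within the list), among them the antiviral genes Oas2 (-3.79 ± 0.90, edgeR adjusted p = 0.0273), Isg15 (-3.04 ± 0.61, adjusted p = 0.0135) and Ifit3 (-2.08 ± 0.47, adjusted p = 0.0233). Camera gave the interferon response list adjusted p = 2.91e-07, or 0.18 at an estimated correlation. Of 36 cell cycle genes 15 rose and 1 fell (24 and 1 adjusted within the list), Ccnb2 (4.77 ± 0.93, edgeR adjusted p = 0.0122) and Top2a (4.32 ± 1.00, adjusted p = 0.0246) among the higher and Kif23 (-3.77 ± 1.01, adjusted p = 0.0424) the lower. The cell cycle list had camera adjusted p = 4.12e-08, or 0.394 at an estimated correlation. Of 30 disease-associated genes 11 rose and 1 fell (22 and 3 adjusted within the list), Csf1 the lower (-3.91 ± 0.83, edgeR adjusted p = 0.0173). Camera gave the disease-associated list adjusted p = 1.93e-05, or 0.394 at an estimated correlation. Of 25 homeostatic genes 8 rose and 1 fell (16 and 1 adjusted within the list), Selplg the lower (-2.07 ± 0.56, edgeR adjusted p = 0.0434). Camera gave the homeostatic list adjusted p = 6.68e-05, or 0.394 at an estimated correlation. Of 12 MHC class II genes 5 rose and 1 fell (9 and 1 adjusted within the list), the costimulatory gene Cd80 the lower (-2.37 ± 0.58, edgeR adjusted p = 0.0307). Camera gave the MHC class II list adjusted p = 0.000968, or 0.386 at an estimated correlation. Of 23 lipid transport genes 9 rose (12 adjusted within the list). Camera gave the lipid transport list adjusted p = 6.97e-05, or 0.353 at an estimated correlation. Of 24 phagocytic receptor genes 9 rose and 1 fell (10 and 3 adjusted within the list). Camera gave the phagocytic receptor list adjusted p = 0.00372, or 0.185 at an estimated correlation. Neutrophil marker transcripts summed to 4422 ± 306 CPM, erythroid ones to 0.276 ± 0.0455 CPM, T and NK cell ones to 454 ± 53.6 CPM and B cell ones to 449 ± 10.9 CPM. Sums of astrocyte markers, mostly Mfge8, were 1275 ± 84.7 CPM against 92.4 ± 12.7 CPM in sham. Neuron ones, mostly Camk2a and high in replicate 2 alone, summed to 507 ± 691 against 24.2 ± 5.27 CPM. Mural ones summed to 815 ± 808 against 115 ± 66.5 CPM. Dendritic cell ones summed to 1066 ± 269 CPM, against the sham sum given with day 21.

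Of 22 immediate early genes at day 90 2 rose and 7 fell (2 and 12 adjusted within the list), Klf2 (-5.08 ± 0.80, edgeR adjusted p = 0.0047) and Egr1 (-3.89 ± 0.65, adjusted p = 0.00579) among the lower, and the higher pair, Hspa1a and Hspa1b, share sequence with a near-identical copy. Camera gave the immediate early list adjusted p = 0.000156, or 0.44 at an estimated correlation. Il1b (-2.42 ± 0.63, edgeR adjusted p = 0.0381) and Nlrp3 (-4.00 ± 0.76, adjusted p = 0.011) fell. For the 48 ribosomal protein genes no member was called by edgeR (10 at an unadjusted p under 0.05, 10 by DESeq2, 2 by limma-voom and 0 adjusted within the list), with a median of -1.13. The ribosomal protein list had camera adjusted p = 0.00012, or 0.593 at an estimated correlation. Of 41 oxidative phosphorylation genes 1 fell (none adjusted within the list), Atp5l (-3.53 ± 0.92, edgeR adjusted p = 0.0391), with a median of -1.21. Camera gave the oxidative phosphorylation list adjusted p = 0.000424, or 0.618 at an estimated correlation. The T cell genes Cd4 (5.14 ± 0.75, edgeR adjusted p = 0.00402) and Cd8a (4.36 ± 1.16, adjusted p = 0.0408) rose and Gzma fell (-5.56 ± 0.98, adjusted p = 0.00766). Of 18 T and NK cell genes 4 rose and 1 fell (8 and 2 adjusted within the list). Camera gave the T and NK cell list adjusted p = 0.0115, or 0.431 at an estimated correlation. Of 17 monocyte genes 3 fell (9 adjusted within the list), Ly6c2 (-4.08 ± 0.98, edgeR adjusted p = 0.0284) among them. The monocyte list had camera adjusted p = 2.79e-05, or 0.394 at an estimated correlation. Of 15 neutrophil genes 4 fell (2 higher and 8 lower adjusted within the list). Camera gave the neutrophil list adjusted p = 0.0109, or 0.578 at an estimated correlation. Of 4 erythroid genes 2 fell (3 adjusted within the list). The erythroid list had camera adjusted p = 6.64e-05, or 0.136 at an estimated correlation. Neuron genes 1 fell (1 adjusted within the list) of 12, the synaptic gene Nrgn (-5.61 ± 1.27, edgeR adjusted p = 0.0225). The neuron list had camera adjusted p = 0.956. In total 1089 genes passed, 710 higher and 379 lower, with limma-voom 725 higher and 649 lower, against 2599 with DESeq2, 451 against a minimum fold change of 2, 1796 with day 21 left out of the fit and 2620 with only the 4 libraries fitted. With 1 library left out the count was 187 or 129 without sham replicate 1 or 2, 1789 or 1800 without day 21 replicate 1 or 2, 685 or 694 without day 60 replicate 1 or 2 and 259 or 243 without day 90 replicate 1 or 2.

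**Figure D4:**
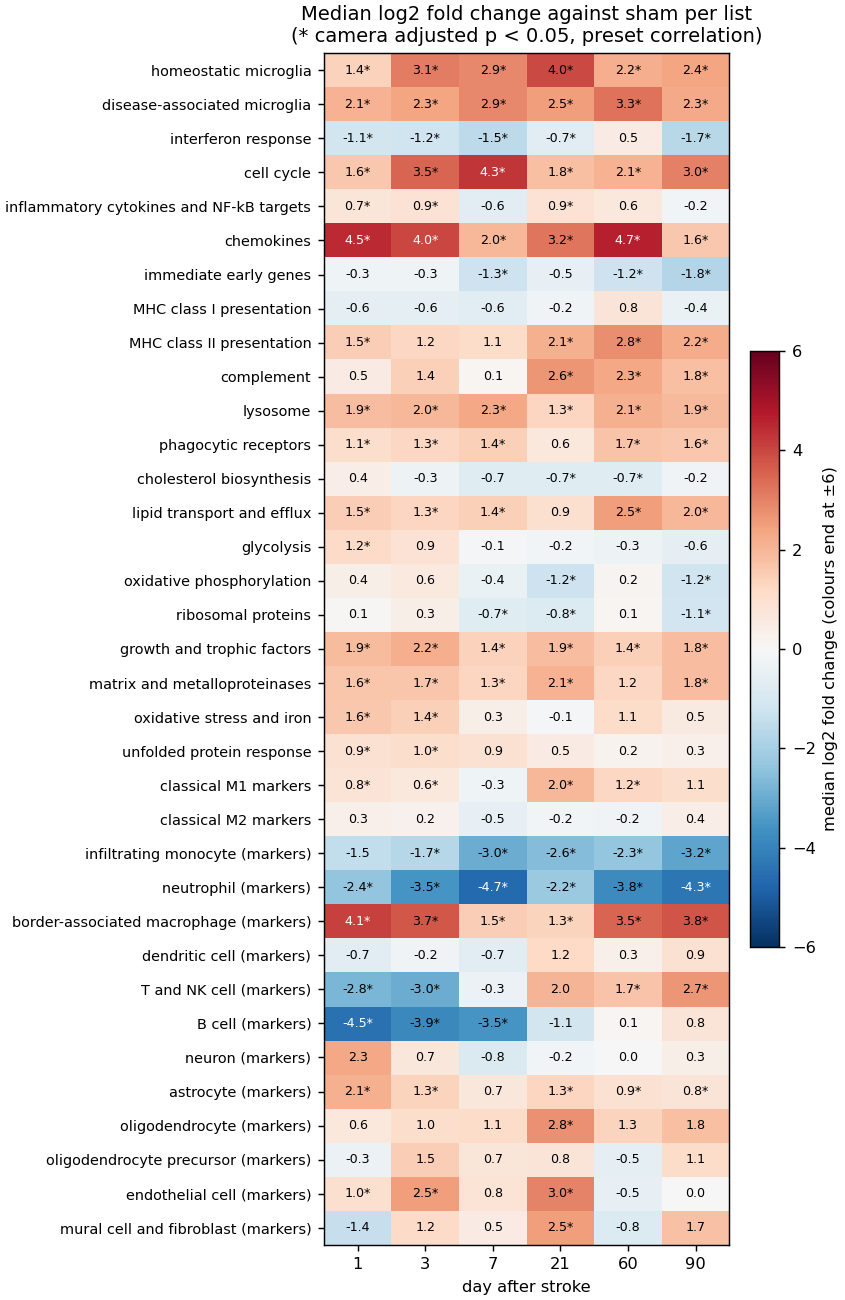
Bounded median log2 fold change against sham of each list except the erythroid (vertical) at each time (horizontal), in colour, with an asterisk where the camera adjusted p was under 0.05, of which 0 hold at an estimated correlation (lowest adjusted p = 0.0906). The cell cycle list has its highest median at day 7, 4.27, and the neutrophil list its lowest there, -4.65.

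Steps between neighbouring times asked when the profile moved. Il23a, a subunit of interleukin 23, fell from day 3 to day 7 (-6.94 ± 0.77, edgeR adjusted p = 0.0145), from 33.4 ± 19.9 CPM to 0.274 ± 0.0241 CPM, and was the 1 gene called in that step. From day 21 to day 60 the 3 genes called were Mmp12 (6.02 ± 0.81, edgeR adjusted p = 0.0369), the scavenger receptor gene Cd36 (4.94 ± 0.65, adjusted p = 0.0369) and Pparg (4.32 ± 0.48, adjusted p = 0.016), all higher at day 60, with Pparg going from 6.75 ± 2.61 CPM to 134 ± 12.1 CPM. The other steps gave 0 calls with edgeR: day 1 to 3 with 348 genes at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom, day 7 to 21 with 1340, 373 and 4, and day 60 to 90 with 442, 21 and 0. For day 3 to 7 DESeq2 gave 115 and limma-voom 5. Single libraries left out gave edgeR counts of 6 without day 1 replicate 1, 0 without day 3 replicate 1, 0 without either day 7 library and 5 without either day 21 library. From day 7 to 21 edgeR gave 10 without either day 1 library, 2 without either day 3 library and 259 or 8 without day 21 replicate 1 or 2. From day 21 to 60 it gave 1 without either sham library, 6 without either day 1 library, 0 without either day 7 library, 360 or 0 without day 21 replicate 1 or 2, 0 without either day 60 library and 0 without either day 90 library, DESeq2 347 and limma-voom 10.

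The mean of days 21, 60 and 90 was set against that of days 1, 3 and 7 to separate late from early gene expression without sham. Lymphocyte genes led the higher side: Ms4a1 was higher late (6.21 ± 0.56, edgeR adjusted p = 0.000209) with 27.8 ± 21.0 CPM against 0.318 ± 0.191 CPM early (n = 6 libraries each). So were Faim3 (9.74 ± 0.74, edgeR adjusted p = 0.000112) and Ly6d (7.35 ± 0.78, adjusted p = 0.000524). Of 10 B cell genes 7 were higher late (9 adjusted within the list). Camera gave the B cell list adjusted p = 1.74e-12, or 0.0272 at an estimated correlation. Of 18 T and NK cell genes 12 were higher late (14 adjusted within the list), with a median log2 fold change of 3.45. The T and NK cell list had camera adjusted p = 9.78e-17, or 0.0502 at an estimated correlation. Lower late were the monocyte-attracting chemokine genes Ccl2 (-3.89 ± 0.38, edgeR adjusted p = 0.000389) and Ccl7 (-3.74 ± 0.46, adjusted p = 0.00151), the endothelin receptor gene Ednrb (-4.56 ± 0.39, adjusted p = 0.000209) and Pdpn, which encodes podoplanin, (-3.31 ± 0.50, adjusted p = 0.00495). Of 19 chemokine genes 3 were higher late and 4 were lower late (6 and 6 adjusted within the list). The chemokine list had camera adjusted p = 0.644. Of 12 MHC class II genes 1 was higher late (8 adjusted within the list), at a median of 1.26. The MHC class II list had camera adjusted p = 2.35e-05, or 0.272 at an estimated correlation. In the glycolysis list 1 was lower late (1 higher and 9 lower adjusted within the list) of 21, at a median of -0.93. Camera gave the glycolysis list adjusted p = 2.72e-06, or 0.272 at an estimated correlation. In the cell cycle list no member was called by edgeR (10 at an unadjusted p under 0.05, 5 by DESeq2, 2 by limma-voom and 0 adjusted within the list), at a median of -0.85. Camera gave the cell cycle list adjusted p = 1.64e-06, or 0.548 at an estimated correlation. In total 392 genes passed edgeR, 302 higher and 90 lower late, against 1148 with DESeq2, 154 against a minimum fold change of 2 and 679 with day 21 left out. With 1 library left out the count was 190 without day 3 replicate 1, 146 or 181 without day 7 replicate 1 or 2, 899 without day 21 replicate 1, 199 or 202 without day 60 replicate 1 or 2 and 175 or 190 without day 90 replicate 1 or 2.

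**Figure D5:**
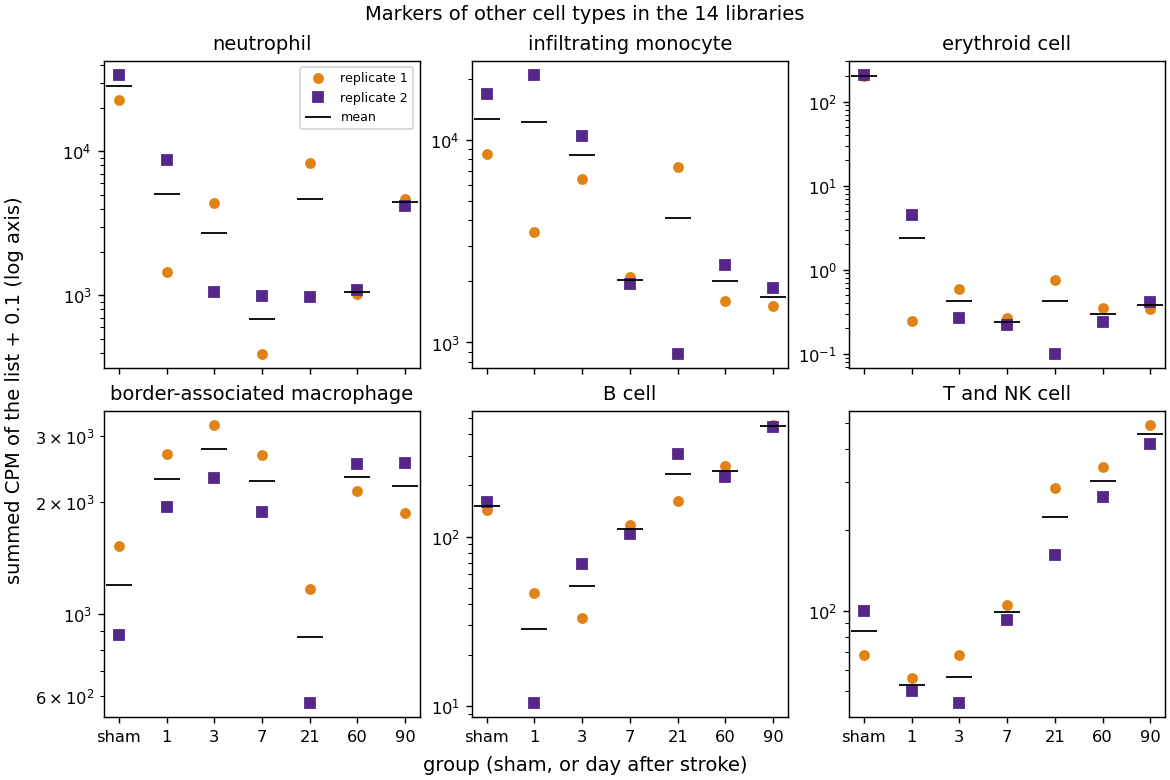
Summed CPM (without TMM factors) + 0.1 of 6 marker lists by group on a log axis, each point 1 library and each bar a group mean. Erythroid sums lie at 204 ± 4.59 CPM in sham and below 5 CPM in each stroke library, and B cell sums run from 28.4 ± 25.5 CPM at day 1 to 449 ± 10.9 CPM at day 90.

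The same late times were also set against sham. Against no count in sham, H2-M2 was at least 1987-fold higher (edgeR adjusted p = 0.00594), Ccl8 at least 1661-fold higher (adjusted p = 0.00523) and Ifnb1 at least 308-fold higher (adjusted p = 0.00192), with late levels of 48.6 ± 39.1 CPM, 52.2 ± 67.3 CPM and 9.15 ± 11.6 CPM (n = 6). Atp6v0d2 rose (12.73 ± 1.93, edgeR adjusted p = 0.00274), and Ccl22, a chemokine gene with 1 count in sham, had 58.9 ± 45.4 CPM late. The erythroid gene Alas2 (-10.56 ± 1.35, edgeR adjusted p = 0.00176), the platelet gene Ppbp (-7.79 ± 1.02, adjusted p = 0.00161) and the stefin genes Stfa2l1 (-7.47 ± 1.33, adjusted p = 0.00774), Gm5483 (-7.08 ± 1.53, adjusted p = 0.0175) and Gm5416 (-9.57 ± 2.06, adjusted p = 0.0208) fell. In total 2218 genes passed edgeR, 1087 higher and 1131 lower, a higher share of 49.0% that was 59.3% with upper-quartile scaling, which moved the median of all genes by 0.174 log2 units. DESeq2 gave 3600 (1993 higher and 1607 lower) and a minimum fold change of 2 gave 873 (517 higher and 356 lower). With 1 library left out the count was 501 or 622 without sham replicate 1 or 2, 1403 or 1292 without day 60 replicate 1 or 2 and 1206 or 1159 without day 90 replicate 1 or 2.

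A joint test over the 7 groups called 999 genes by edgeR. Sham held the highest mean for 357 of them and the lowest for 426, while day 7 held the highest for 109 and the lowest for 194, and days 60 and 90 the highest for 142 and 152. DESeq2 called 3501, limma-voom 651 and the fit without the day 21 libraries 1797. Without single libraries edgeR called 224 or 227 without sham replicate 1 or 2, 463 or 492 without day 7 replicate 1 or 2, 2185 without day 21 replicate 1, 438 or 377 without day 60 replicate 1 or 2 and 352 or 344 without day 90 replicate 1 or 2.

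Genes called at neighbouring times overlapped in part. Days 1 and 3 shared 425 higher and 161 lower genes, days 3 and 7 602 and 337, days 7 and 21 500 and 161, days 21 and 60 407 and 110, and days 60 and 90 515 and 221, while days 1 and 90 shared 297 and 84. Independent lists of those sizes would share 22.9 and 5.84, 50.5 and 24.0, 48.5 and 11.2, 34.3 and 5.76, 35.2 and 11.0, and 22.6 and 5.20 genes in the same order. Unchanged groups simulated 10 times with a shared sham had a mean overlap of 0 or 0.1 genes, not a measure of what shared controls add to real calls. Log2 fold changes correlated with r of 0.796, 0.833, 0.757, 0.736, 0.854 and 0.597, against 0.505, 0.4997, 0.504, 0.516, 0.519 and 0.514 simulated. Their covariance was 4.01, 4.78, 4.65, 4.26, 4.84 and 3.15, against 0.783, 0.774, 0.771, 0.784, 0.773 and 0.772 simulated. Part of the excess over independent lists and simulation may come from the shared sham's own differences. The simulation lacks these, and a split of sham leaves 1 library per side.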

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

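The tests of a swap and of a lower microglial share in sham, and the 3 tests on the day 21 libraries, were chosen after the result was seen. Of the steps between neighbouring times, 4 genes differed past the test threshold. Il23a fell from day 3 to day 7 by a log2 fold change of -6.94 ± 0.77 (edgeR adjusted p = 0.0145). From day 21 to day 60 Cd36 rose by 4.94 ± 0.65 (edgeR adjusted p = 0.0369), Mmp12 by 6.02 ± 0.81 (adjusted p = 0.0369) and Pparg by 4.32 ± 0.48 (adjusted p = 0.016). The count of genes called from day 3 to day 7 went from 1 to 6 without day 1 replicate 1, 0 without day 3 replicate 1, 0 without either day 7 library and 5 without either day 21 library, and that from day 21 to day 60 went from 3 to 1 without either sham library, 6 without either day 1 library, 0 without either day 7 library, 360 or 0 without day 21 replicate 1 or 2, 0 without either day 60 library and 0 without either day 90 library. The T and NK cell list was higher late than early, with a median log2 difference of 3.45 (camera adjusted p = 9.78e-17, adjusted p = 0.0502 with an estimated correlation).

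Sham libraries held transcripts of blood cells: neutrophil markers summed to 28338 ± 7799 CPM in sham, with S100a9 at 9129 ± 6702 CPM, S100a8 at 7804 ± 6232 CPM and Mmp9 at 4369.5 ± 574 CPM, and to at most 5067 ± 5117 CPM on average at any time after stroke, at day 1. A swap of 1 sham library with a stroke library is argued against, since the highest erythroid sum in a stroke library was 2.21% of that in the lower sham library (4.43 against 200.5 CPM), while an exchange of both with both of another group would leave that value as it is. A lower share of microglia in sham cannot be told apart: the medians of markers of neurons, glia and vessel cells and of neutrophils moved in opposite directions at all 6 times, against a rise of both alike, but by more than their interquartile ranges at 3 of 6. Cells of another type in the sham sort are a candidate source: the neutrophil markers followed each other over the 14 libraries with a median correlation of 0.552, against 0.0454 for matched random lists (95th percentile 0.212), although the homeostatic list reached 0.575, so the measure also rises for a change within the sorted cells. What stays open is also whether the surgery, the sort or the animals differed in sham, and every comparison with sham carries it.

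Genes also differed by replicate number, 1306 with edgeR, 692 higher and 614 lower in replicate 2, led by H2-Q1 at 12.94 log2 units (edgeR adjusted p = 7.71e-07). Depth alone is argued against, since 95.3% of them were still called in the same direction after thinning all libraries to equal totals. Reads shared between near-identical genes and counted differently are a candidate explanation for the largest differences: of the genes at least 8-fold higher in replicate 2 19.8% had a near-identical copy, 13.1 times the 1.51% of genes not called, and 48 of 242 genes had one. A bias by length or GC content cannot be told apart from none here, because the larger of the rank correlations, that with length, was -0.113 over 13813 genes, a size between the bounds set for the test. No biological explanation was tested, since the labels give the numbers no meaning.

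The day 21 libraries had the lowest correlation of the 7 pairs, 0.824 against at least 0.885 elsewhere, while by chi-square per degree of freedom day 1 differed more (1498 against 1312). The difference shared by the other groups between replicates 2 and 1 cannot be told apart: with it removed the root mean square difference at day 21 was 2.003 log2 units against at most 1.76 in another group, a gap under the standard deviation of 0.339 over those 6. Different shares of other cells may contribute: 3 of 4 lists lay outside the range of the other groups, replicate 1 minus replicate 2 being 3.42 log2 units for monocyte, 4.0 for neutrophil and 3.43 for dendritic cell markers and -1.33 for homeostatic genes. This cannot be told apart from a difference between the animals, because the homeostatic genes, though lower in replicate 1 as a mixture predicts, lay within the -1.40 to 0.887 of the other groups. A wrong label stays open as well, because replicate 1 correlated at 0.938 with a library of another time but 10 of the other 12 libraries did so by the same measure.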

How the results depend on the processing

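Leaving out the day 21 libraries or genes with a near-identical copy was chosen after seeing the data. The majority of higher or lower genes turned with limma-voom at days 3 and 7, without sham replicate 2 at day 7, with RLE and the block at day 7 (1378 higher and 1399 lower), with only the libraries compared at day 60, and late against sham with DESeq2, upper-quartile scaling, glmTreat, without the day 21 libraries and without either day 1, 60 or 90 library or day 21 replicate 2. Leaving out genes with a copy, RLE or upper-quartile scaling and no filter moved no count by over 1.5 times. With DESeq2 the genes called at days 1, 3, 7, 21, 60 and 90 against sham were 1848, 2639, 3172, 2461, 2653 and 2599, those of the 5 steps in order 5, 115, 373, 347 and 21, between early and late times 1148, late against sham 3600 and over the 7 groups 3501, while overlaps were 1592 for days 1 and 3, 2085 for days 3 and 7, 1678 for days 7 and 21, 1395 for days 21 and 60, 1812 for days 60 and 90 and 1080 for days 1 and 90. With glmTreat they were 266, 504, 790, 389, 409 and 451 against sham, 1 from day 21 to day 60, 154 between early and late times and 873 late against sham, which follows from its minimum fold. Without the day 21 libraries they were 1093, 1802, 1749 and 1796 at days 1, 3, 60 and 90, 5 from day 3 to day 7, 679 between early and late times and 1797 over all groups. With limma-voom 1696 were called at day 21, 5 from day 3 to day 7, 4 from day 7 to day 21, 10 from day 21 to day 60 and 651 over the 7 groups. With only the libraries compared 0 were called at day 21 and from day 21 to day 60 with edgeR, 1675 at day 60, 2620 at day 90 and 31 from day 3 to day 7. Thinned libraries gave 2 from day 7 to day 21, the stricter filter 1 from day 21 to day 60, and set tests with an estimated correlation 1 call. Apart from the minimum fold the cause was not tested.

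Replicate numbers did not pair the samples by the rule fixed for it, since 1 of 21 correlations of same-numbered deviations, 0.0710, lay under 0.1, although the highest was 0.677 and the median 0.374. With the replicate number as a block 1195, 2002, 2766, 1584, 1953 and 2006 genes were called at days 1, 3, 7, 21, 60 and 90 against sham, 2 from day 7 to day 21, 7 from day 21 to day 60, 680 between early and late times and 1635 over the 7 groups, and overlaps were 1099 for days 1 and 3, 1623 for days 3 and 7, 1172 for days 7 and 21, 938 for days 21 and 60, 1349 for days 60 and 90 and 707 for days 1 and 90. The block with RLE scaling gave 1220, 2059, 2777, 1656, 1975 and 2018, then 2, 7, 676 and 1666, and 3357 late against sham. Of the 139 camera calls 138 held with the block, 138 with RLE scaling and 98 with fry, and 131 of 135 held without shared members.

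With each library left out in turn, counts ranged from 76 to 1098 at day 1, 225 to 1815 at day 3, 355 to 2457 at day 7, 68 to 2410 at day 21, 132 to 1750 at day 60 and 129 to 1800 at day 90, from 0 to 0 for days 1 to 3, 0 to 6 for days 3 to 7, 0 to 259 for days 7 to 21, 0 to 360 for days 21 to 60 and 0 to 0 for days 60 to 90, and from 146 to 899 between early and late times, 501 to 3304 late against sham and 224 to 2185 over the 7 groups. Of 557 fold changes of named genes called against sham, 443 lost the call without at least 1 library, and 0 reversed then or with DESeq2, RLE scaling, no filter or the block.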

Other observations

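The split of early and late libraries was tested as fixed in advance, and the genes named singly here were chosen after their values were seen. Mpo, the myeloperoxidase gene, had 334 and 346 CPM in the day 90 libraries and 3.09 and 0.380 CPM in sham, and Elane, neutrophil elastase, had 99.6 and 108 CPM against 1.64 and 0.701 CPM. S100a8 had 92.9 and 129.5 CPM at day 90 and 3397 and 12210 CPM in sham. Against sham at day 90 Prtn3, the proteinase 3 gene, rose by 3.34 ± 0.80 (edgeR adjusted p = 0.0291) and Ms4a3, a gene of granulocyte and monocyte precursors, by 4.69 ± 1.25 (adjusted p = 0.0421), while Mpo at 7.67 ± 2.10 (adjusted p = 0.0557) and Elane at 6.51 ± 1.85 (adjusted p = 0.0587) did not pass. Ms4a3 was also higher in the late than in the early libraries, by 4.79 ± 0.75 (edgeR adjusted p = 0.0059).

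Some genes of other cell types were high in single libraries or in the libraries of 1 replicate number. Camk2a, a kinase gene of excitatory neurons, had 1760 CPM in day 60 replicate 2 and 942 CPM in day 90 replicate 2 and at most 5.68 CPM in the other 12, and Pdgfrb, a pericyte receptor gene, had its highest values in the same 2 libraries. Ly6c1, of vascular and myeloid cells, lay between 0.0606 and 4.87 CPM in the replicate 1 libraries and between 59.6 and 1747 CPM in the replicate 2 libraries. In day 21 replicate 1 the dendritic cell genes Ccr7, Cd209a and Flt3 had 725, 644 and 98.8 CPM, against 15.7, 10.7 and 2.57 CPM in replicate 2.

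Early and late libraries were set against 100 of the 462 splits of the 12 stroke libraries, 6 against 6. The real split called 280 of 12732 genes in a fit of these 12 alone. Of the 100 splits 1, itself, called as many, and the highest other called 9. Chance over single libraries is argued against, but the real split keeps each day whole, so another grouping of days is not. A split by replicate number, not drawn, called 940 genes, which points to a structure of the samples by that number. Of the drawn splits 41 were balanced by replicate number and 1 of them, the real split, called as many, and with the replicate number as a block the comparison called 680 genes.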
